A study of Homo sapiens with 18 samples.

How the data were processed

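The 3 histone marks H3K27ac, H3K4me1 and H3K4me3 were profiled by ChIP-seq in 4 conditions of human lung adenocarcinoma cells. The 18 samples comprised 13 immunoprecipitated libraries with a peak file and 5 input libraries, whose files were not analysed here. LCC H3K27ac had 2 libraries that the labels number as biological replicates, and all other libraries were single. Per the labels, cells were crosslinked with formaldehyde, and antibodies were from Active Motif (H3K27ac), Abcam (H3K4me1) and Millipore (H3K4me3). Groups were taken from the sample titles.

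Per the submitters' processing notes, Bowtie2, SAMtools, deepTools and the hg19 build were used. The peak caller, its version, its control and its settings are not given in the sources used here. Each deposited file lists peak summits 1 bp wide with a score per peak, and its layout is that of MACS summit files. The authors' deposited score is read as the −log10 of a p-value or q-value: the lowest value in any file, 1.30107, lies just above 1.30103, the −log10 of 0.05. Whether it is a p or a q value was not settled. The peak names in each deposited file carry 1 library name, so peaks were called per library. The score rises with depth and was used to rank or filter peaks within a list. It was also compared between lists for the flanking summits of lost elements, where depth can affect the outcome. The files hold no peak widths or read counts, so a wide peak is represented by its single summit, and the depth of each library is unknown.

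Summits on chromosomes 1 to 22 and X were used, which left out between 29 and 238 summits per library. A summit was shared when the other list had one within 500 bp. The share expected without correspondence was taken from a list shifted by 2 Mb. H3K4me3 summits of the 4 conditions were merged within 1000 bp into elements that stand for promoters, because the reference at hand is of another build than hg19 and no coordinates were converted. For the same reason no gene is named, the gene lists fixed beforehand could not be tested, and enhancer-like elements carry no condition on the distance to a transcription start. This is the fallback fixed before the data were examined.

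An element was marked when a summit lay within 1000 bp. It was gained when the other condition marked it with a score at or above the median over that library's marked elements and no LCC library of that mark did. It was lost when every LCC library marked it, the highest LCC score was at or above that library's median, and the other condition did not mark it. Enhancer-like elements were H3K27ac summits with an H3K4me1 summit and without an H3K4me3 summit of the same condition within 1000 bp, merged within 1000 bp. In LCC a summit of both replicates was required. Elements were named by a rule fixed beforehand, the 5 gained and 5 lost with the highest score per comparison and mark, the lower of the 2 replicate scores being taken for LCC H3K27ac. Dense regions joined H3K27ac summits within 12.5 kb, and the first 20 of each library were compared with the first 100 of the others.

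Several steps were added after the data were seen. Gained and lost elements were recounted with no summit allowed within 5, 10 or 25 kb, and the same ranking then named the elements. Distal elements were called new or lost when no H3K27ac summit lay within 10 kb, and their H3K4me1 was looked up within 1 kb in the other condition. Lost elements with a TGFb summit between 1 and 10 kb away were set against strong LCC elements marked in TGFb. Flanking summits of lost elements were compared with the element's lower LCC score, and a stronger one was held able to be the summit of a joined peak within 50 kb. TGFb elements with a summit of one LCC replicate within 1 kb and none of the other within 10 kb gave the H3K4me1 share of missed peaks. The TGFb H3K4me1 list was reduced to the number of SO1 peaks, and the SO1 summits left in the blocks were compared with the median score of their list. Blocks of 500 kb with at least 15 summits of the 3 marks in one condition (replicate 1 for LCC H3K27ac) and at most 5% of that number in another were listed.

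No test was run, since each condition compared with LCC has 1 library per mark. Shares have Wilson 95% intervals, and values averaged over the LCC replicates have an SD over n = 2. The 2 replicate lists differ in length, and this SD includes that difference. H3K27ac comparisons were set beside that of the 2 LCC replicates, which the other marks lack. The alternatives fixed beforehand were a distance of 250 bp, scores of at least 10, lists of equal length, a window of 2500 bp, no strength condition, a kept distance of 500 bp and leaving out each LCC replicate. The gain and loss calls were run on simulated data, in which 200 gained and 200 lost H3K27ac elements were planted among 39776 in a list derived from LCC replicate 2 with summits moved at random. All 200 of each were recovered under both distances. The planting largely fixed this, as gains lay over 12 kb from LCC summits and losses had all nearby summits removed. The list was a moved copy of replicate 2, so the counts below leave out differences between libraries. Of the elements not planted, 21 were called gained and 119 lost at 1 kb, and 0 and 43 at 10 kb. Of the lost ones, 62 and 43 lay within 13 kb of a planted loss, for which summits up to 12 kb away had been removed. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.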

Results

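The study mapped 3 histone marks by chromatin immunoprecipitation and sequencing (ChIP-seq) in human lung adenocarcinoma cell lines. H3K27ac marks active promoters and enhancers, H3K4me1 marks enhancers and the flanks of promoters, and H3K4me3 marks promoters. The 4 conditions were H2087-LCC (here LCC), LCC treated with 100 nM of the cytokine TGF-β1 for 4 days as the labels state it (here TGFb; the dose is unusually high for this cytokine and could not be checked), H2087-LCC-SO1 (here SO1) and H2030. H2087 and H2030 are separate lung adenocarcinoma lines, and the labels give a simpler growth medium for H2030 than for the other conditions, so cell line and medium cannot be separated in that comparison. The series title names the suppression of dormant metastasis reactivation by STING, a sensor of cytosolic nucleotide signals, as its subject. LCC H3K27ac was profiled in 2 biological replicates and each other combination of condition and mark in 1 library, so the comparisons carry no p-value and the LCC replicates are the only measure of experimental error. The 13 files hold 947675 peak summits. H3K27ac lists held 50663 and 62986 summits in LCC replicates 1 and 2, 68118 in TGFb, 56324 in SO1 and 52534 in H2030. H3K4me1 lists held between 128146 summits in SO1 and 143843 in TGFb, and H3K4me3 lists between 25691 in H2030 and 28889 in TGFb. Read depth per library is unknown. All positions are hg19 coordinates, and each summit's score is the −log10 of the peak caller's p or q value. Scores rank peaks within their own list, except where a flanking summit is set against the LCC score of a lost element.

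H3K27ac summits were divided between promoter and distal sites in all conditions. Between 32.3% of H3K27ac summits (LCC replicate 2 and TGFb) and 39.1% (LCC replicate 1 and SO1) had an H3K4me3 summit of the same condition within 1 kb. A further 46.0% in H2030 to 55.8% in TGFb had H3K4me1 but no H3K4me3 within that distance. Neither mark lay within 1 kb of 9.53% of the SO1 and 18.8% of the H2030 H3K27ac summits. The H3K4me3 summits of the 4 conditions merged into 39776 elements with a median length of 54 bp, which stand for promoters below. An element can rest on a weak H3K4me3 summit of a single condition. Of these, 16445 carried H3K4me3 in all 4 conditions. H2030 alone carried 6378, SO1 alone 2886, TGFb alone 1948 and LCC alone 884.

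The LCC replicates set the scale for the H3K27ac comparisons. Of the replicate 1 summits, 69.8% (Wilson 95% interval 69.4 to 70.2) had a replicate 2 summit within 500 bp, and 56.1% (55.7 to 56.5) of the replicate 2 summits had a replicate 1 summit. A list shifted by 2 Mb gave 2.54% and 2.04%. With lists reduced to equal numbers of their highest-scoring peaks, the shares were 65.9% and 65.4%. Only 194 summits lay at the identical base in both, 0.383% of replicate 1. These intervals, and all others below, cover counting error only.

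The comparison of TGFb with LCC asks which regulatory sites change when LCC cells are exposed to TGF-β1. TGFb kept the highest shares of LCC summits among the 3 conditions. At promoter elements, 24 gained and 37 lost strong H3K27ac (scores at or above the median) against both LCC replicates when no summit was allowed within 10 kb. Against replicate 1 alone 84 gained and 41 lost it, beside 2 and 5 for replicate 2 against replicate 1. Against replicate 2 alone 32 gained and 15 lost it, beside 5 and 2 for replicate 1 against replicate 2. The excess of losses thus held only when both replicates were used. Distal elements were called without a strength condition, and 5582 of the 33819 enhancer-like elements of TGFb, or 16.5%, had no LCC H3K27ac summit of either replicate within 10 kb. Most of these new elements, 77.2% (76.1 to 78.3), already carried H3K4me1 in untreated LCC. The share was 91.0% among TGFb elements with LCC H3K27ac within 1 kb, and 10.6% with a shifted list. Each element carried TGFb H3K4me1 by definition, and of all TGFb H3K4me1 summits 61.6% had an LCC one within 500 bp. The shifted list is therefore a low baseline, and part of the 77.2% may follow from how elements were chosen. H3K27ac peaks missed in LCC and new H3K27ac cannot be told apart here.

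Of the LCC H3K4me3 summits, 90.3% (89.9 to 90.7) had a TGFb summit within 500 bp. The shares were 62.1% for H3K4me1 and 63.4% ± 1.36 (SD, n = 2 LCC replicates) for H3K27ac. The H3K27ac share lay between the replicates' own values of 56.1% and 69.8%. At equal list lengths, 59.9% of replicate 1 and 63.5% of replicate 2 summits were found in TGFb, below the 65.9% and 65.4% that the replicates shared with each other. In the reverse direction, 81.6% of the H3K4me3, 61.6% of the H3K4me1 and 52.5% ± 7.02 (SD, n = 2) of the H3K27ac summits of TGFb were found in LCC.

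**Figure D1:**
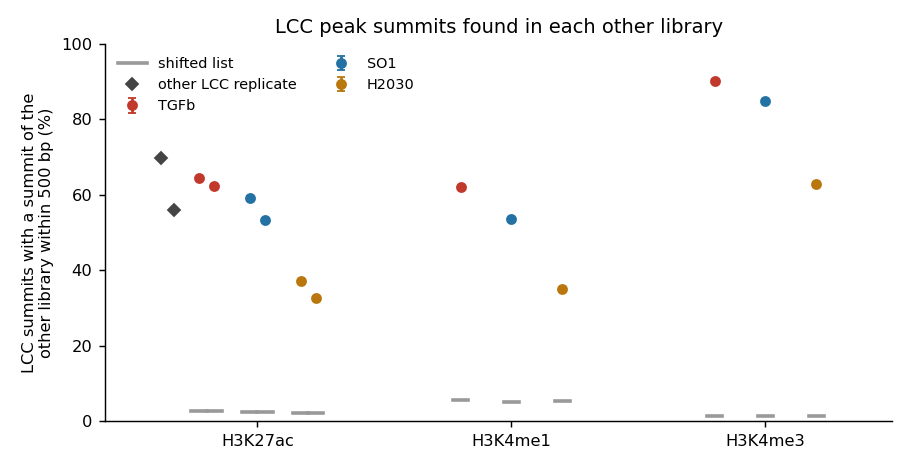
Share of LCC peak summits (%, vertical axis) with a summit of the other library within 500 bp, by mark, for TGFb, SO1 and H2030; H3K27ac has a point for each LCC replicate, diamonds are the replicates against each other, whiskers are Wilson 95% intervals mostly smaller than the points, and grey bars are the share found with a shifted list. H3K4me3 was shared most, at 90.3%, 85.0% and 62.7%, and H2030 lay lowest for every mark.

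By the rule set before the data were examined (a strong summit within 1 kb of an element on one side, none on the other), 158 elements gained and 463 lost H3K27ac in TGFb, and 136 gained and 130 lost H3K4me3. Without the strength condition the H3K27ac balance turned to gain, with 1976 gained and 1059 lost, and the H3K4me3 counts were 4235 gained and 1679 lost. The H3K27ac counts of the rule need both LCC replicates to lack or to carry the mark. Against replicate 1 alone, TGFb gave 371 gained and 661 lost, beside 227 and 441 for LCC replicate 2 against replicate 1. Against replicate 2 alone, TGFb gave 358 and 519, beside 441 and 227 for replicate 1 against replicate 2. The 358 gains thus lay below the 441 that the other LCC replicate gave. Of the 463 lost H3K27ac elements, 92.0% had a TGFb H3K27ac summit within 10 kb, as did all of the 130 lost H3K4me3 elements for H3K4me3. When no summit was allowed within 10 kb, a distance chosen after seeing the data, 4 elements gained and 0 lost H3K4me3 in TGFb, beside the 24 and 37 for H3K27ac.

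The 5 strongest elements of the first rule in each direction and mark all had a summit within 10 kb, so the elements named here follow the same ranking under the 10 kb distance. The strongest H3K27ac gain in TGFb, at 12:104982043-104982355, had a TGFb score of 338, while the nearest LCC summit of replicate 1 lay 15867 bp away. Its TGFb H3K4me3 score was 98.0, with the nearest LCC H3K4me3 summit 82789 bp away, and LCC carried H3K4me1 there with a score of 15.3. The next gains lay at 12:69799565-69799667 (score 274), 10:49197771 (252), 19:49541923 (242) and 20:60500386-60500787 (215). TGFb H3K4me3 scored 5.41 at the first of these, 5.47 at 19:49541923 and 98.4 at 20:60500386-60500787. At 10:49197771 TGFb and LCC had no H3K4me3 within 1 kb, and the element rests on an H2030 H3K4me3 summit (11.2). All 5 gains carried H3K4me1 in LCC, with scores from 2.57 to 33.3. The strongest H3K4me3 gain, at 5:136834834-136834884, scored 423 in TGFb and 393 in H2030, with the nearest LCC H3K4me3 summit 254640 bp away. A TGFb-new distal H3K27ac element stood nearby at 5:136805815, with a score of 355 and LCC H3K4me1 of 15.1.

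Of the 37 H3K27ac losses in TGFb, 22 had no H3K4me1 summit of any condition within 10 kb, which held for 22 of all 12281 strong LCC elements (0.179%). The other 15 had a flanking TGFb summit at or above the element's lower LCC score, between 10953 and 38902 bp away. These included the strongest loss, 1:150551422-150551787, with LCC scores of 229 and 423, which kept H3K4me3 with 531 in LCC and 581 in TGFb. No lost element stood outside both groups.

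**Figure D2:**
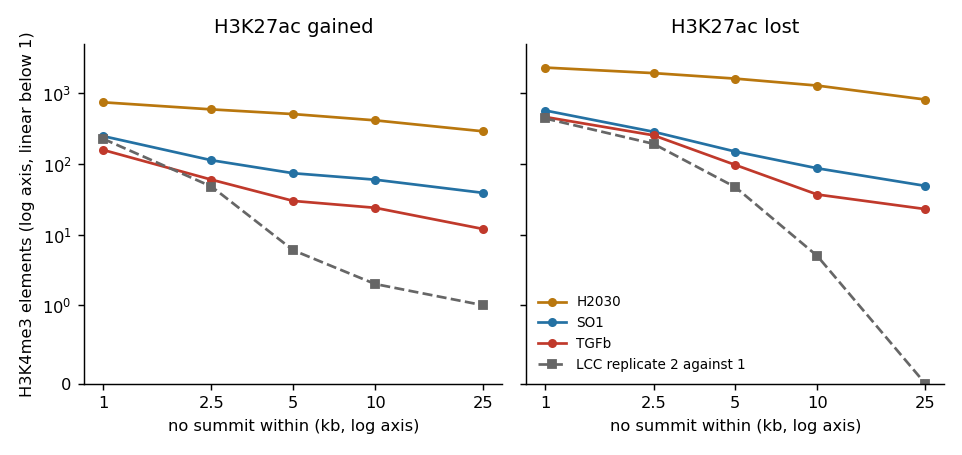
Number of H3K4me3 elements (vertical log axis, linear below 1) that gained or lost H3K27ac against LCC when no summit was allowed within the distance on the horizontal log axis (kb), for H2030, SO1, TGFb and, dashed, LCC replicate 2 against replicate 1. The solid lines need both LCC replicates and the dashed line compares single libraries. At 10 kb replicate 2 against replicate 1 gives 2 gained and 5 lost, and the reverse gives 5 and 2. TGFb gives 84 and 41 against replicate 1 alone and 32 and 15 against replicate 2 alone.

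Enhancer-like elements, H3K27ac summits with H3K4me1 and without H3K4me3 within 1 kb, numbered 16974 in LCC, where both replicates were required, and 33819 in TGFb. TGFb kept 84.9% of the LCC elements. Elements defined from replicate 1 alone were kept at 81.1% in replicate 2 and 76.1% in TGFb, and those from replicate 2 alone at 59.1% in replicate 1 and 73.5% in TGFb. Of the replicate 1 elements, 8.35% had no TGFb summit within 10 kb and 7.04% no replicate 2 summit, while 8.87% of the replicate 2 elements had no TGFb summit and 19.2% no replicate 1 summit. Of the TGFb elements, 18.9% had no replicate 2 summit within 10 kb, against 7.04% of the replicate 1 elements, and 29.6% had no replicate 1 summit, against 19.2% of the replicate 2 elements. The 817 LCC elements without a TGFb summit within 10 kb kept H3K4me1 in 87.8% (85.3 to 89.8), against 93.1% of the kept elements. Without replicate 1 the lost elements numbered 2556 (78.8%), and without replicate 2 they numbered 1748 (79.1%). The strongest new distal element, 17:42665239, scored 411 in TGFb for H3K27ac, with H3K4me1 scores of 28.2 in LCC and 73.2 in TGFb. Others were 10:32702188 (340), 17:35259420 (311) and 6:11318246 (291), all with LCC H3K4me1 within 1 kb. Without replicate 2, the number of new elements was 10004.

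**Figure D3:**
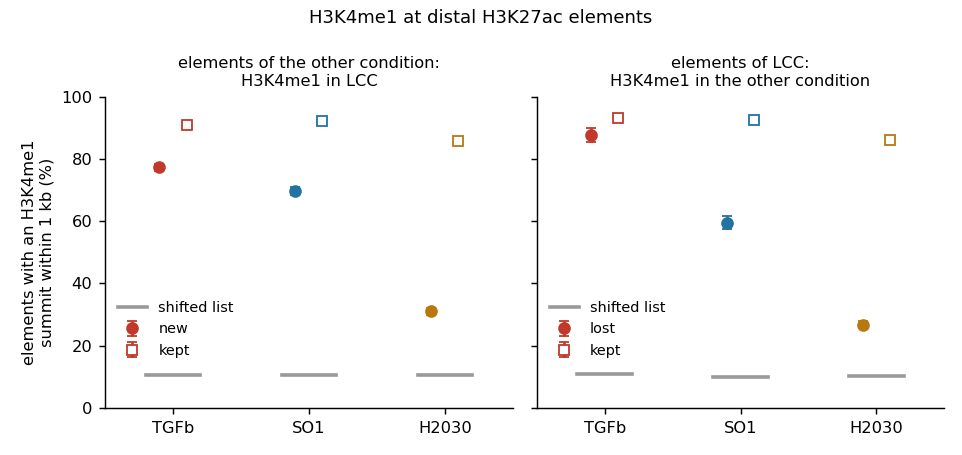
Share of distal H3K27ac elements (%) with an H3K4me1 summit within 1 kb in the condition that lacks the H3K27ac; left, elements of TGFb, SO1 and H2030 looked up in LCC, and right, LCC elements looked up in each condition. Filled circles are elements with no H3K27ac summit within 10 kb in that condition, open squares are kept elements, whiskers are Wilson 95% intervals and grey bars the shifted lists: new elements fall from 77.2% in TGFb to 69.8% in SO1 and 31.1% in H2030. Elements carry H3K4me1 in their own condition by definition, so the shifted lists are a low baseline.

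The comparison of SO1 with LCC sets a subline labelled as H2087-LCC-SO1 against LCC itself. SO1 kept smaller shares of LCC summits and enhancer-like elements than TGFb did. In reverse the order depended on list length: 56.0% of SO1 and 52.5% of TGFb H3K27ac summits were found in LCC, but 57.4% and 61.2% at equal list lengths. Of the LCC distal elements without SO1 H3K27ac within 10 kb, 59.5% kept H3K4me1 in SO1, where TGFb had 87.8%. At the 10 kb distance SO1 gained H3K27ac at 60 promoter elements and lost it at 87, and gained H3K4me3 at 22 and lost it at 9. With either replicate left out the H3K27ac balance turned to gain. The counts were 84 gained and 66 lost without replicate 1, and 126 and 85 without replicate 2.

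Of the LCC summits, SO1 kept 85.0% for H3K4me3 (84.5 to 85.4), 53.7% for H3K4me1 and 56.2% ± 4.14 (SD, n = 2) for H3K27ac. In reverse, 77.3%, 59.6% and 56.0% ± 4.61 (SD, n = 2) of the SO1 summits were found in LCC. At equal list lengths the H3K27ac shares were 57.4% of replicate 1 and 58.1% of replicate 2 summits, below the 65.9% and 65.4% between replicates. The rule set beforehand gave 248 gained and 572 lost for H3K27ac and 175 gained and 178 lost for H3K4me3. Without the strength condition more elements were gained than lost, 2150 and 1683 for H3K27ac and 5427 and 2902 for H3K4me3. Of those called with the condition, 75.8%, 84.8%, 87.4% and 94.9% had a summit within 10 kb.

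Among H3K4me3 gains, 7:70160302-70160359 scored 587 in SO1. The nearest LCC H3K4me3 summit lay 497717 bp away, and TGFb had a weak H3K4me3 summit there with a score of 3.51. H2030 had an H3K4me3 summit with a score of 320 at 7:70159140. The next gains were 11:68133636 (score 564), 11:102618020 (558), 14:35466674 (322) and 12:24715085-24716012 (318). SO1 H3K27ac also lay at the first 3, with scores of 82.7, 248 and 185. The strongest H3K27ac gain, 1:185343178-185343367, scored 308 in SO1 and 150 in TGFb, with the nearest LCC summits 57065 bp and 57459 bp away. Its SO1 H3K4me3 score was only 16.5, against a list median of 183.

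The strongest H3K4me3 loss in SO1 was at 5:8458037-8458058, which scored 558 in LCC and 603 in TGFb. All 3 marks were absent there: the nearest SO1 summits lay 235045 bp (H3K4me3), 234859 bp (H3K27ac) and 170951 bp (H3K4me1) away. The element was absent from H2030 as well, with H3K4me3 58787 bp away. At 10:54074109-54074624 LCC H3K4me3 scored 355, TGFb 407 and H2030 501, and the nearest SO1 H3K4me3 summit lay 80786 bp away. It lies in a 500 kb block without any SO1 summit, described below, where missing DNA and lost marks cannot be told apart. At 15:90358242-90358258, with 425 in LCC and 448 in TGFb, the nearest SO1 and H2030 H3K4me3 summits lay 21979 bp and 5997 bp away. The strongest H3K27ac loss, 3:189023052-189023121, had LCC scores of 155 and 210, TGFb 152 and no SO1 H3K27ac summit within 11312 bp, while an SO1 H3K4me1 summit of score 5.51 lay 613 bp away. Its LCC H3K4me3 score was only 5.61, against a list median of 189. Of the 87 H3K27ac losses, 36 had no flanking SO1 summit as strong as the element, and 5 had no H3K4me1 of any condition within 10 kb.

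SO1 kept 74.0% of the 16974 LCC enhancer-like elements. From replicate 1 alone it kept 66.4%, against 81.1% in replicate 2, and from replicate 2 alone 60.6%, against 59.1% in replicate 1, so the shortfall depends on which replicate is taken. With no summit within 10 kb, 4953 SO1 elements were new and 2128 LCC elements were lost. Loss affected 15.8% of replicate 1 elements, above the 7.04% without a replicate 2 summit, and 17.6% of replicate 2 elements, below the 19.2% without a replicate 1 summit. Of the SO1 elements, 21.1% were new against replicate 2 alone and 30.9% against replicate 1 alone, above the same 7.04% and 19.2%. LCC already carried H3K4me1 at 69.8% (68.5 to 71.1) of the new elements, and SO1 kept it at 59.5% (57.4 to 61.6) of the lost ones. Kept elements had H3K4me1 in 92.0% and 92.6%. Of all SO1 H3K4me1 summits 59.6% had an LCC one within 500 bp, and of all LCC ones 53.7% had an SO1 one. The strongest new distal element, 10:35864502, scored 379 in SO1, with the nearest LCC H3K4me1 summit 27803 bp away, while 12:72689972 (251) and 12:34141664 (248) had LCC H3K4me1 of 12.7 and 8.34. The strongest lost one, 10:33541381, had LCC scores of 205 and 246 and an SO1 H3K4me1 score of 140. The nearest SO1 H3K27ac summit lay 11251 bp away, and the dense region around it, 10:33519246-33630027, held 14 SO1 summits. Flanking summits were compared for promoter elements only, so joined peaks and loss cannot be told apart at lost distal elements. Without replicate 1 the lost elements numbered 5071 (62.3% with H3K4me1). Without replicate 2 they numbered 3312 (50.8%), and the new ones 8160.

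In 500 kb blocks, LCC held at least 15 summits of the 3 marks together, and SO1 at most 5% of that number, in 12 of 3820 eligible blocks, against 1 block for TGFb. The TGFb block, 10:42000001-42500000, held no LCC H3K4me1 summit. The 12 SO1 blocks included 8:13000001-13500000 with 46 LCC summits and 1 in SO1, X:132500001-133000000 with 39 and 1, 8:56000001-56500000 with 35 and 1, and 10:54000001-54500000 with 33 and 0. TGFb held 47, 33, 33 and 44 summits in these blocks. The opposite was seen in 4 of 3799 blocks, the clearest being 7:70000001-70500000 with 39 summits in SO1 and 0 in LCC.

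**Figure D4:**
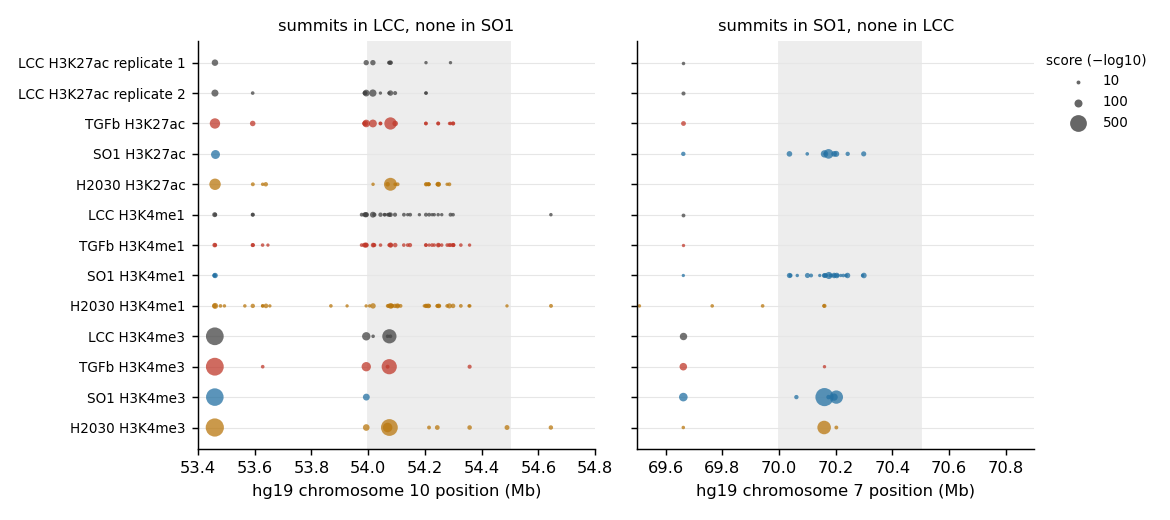
Peak summits of each library, one line each, along hg19 chromosome 10 and chromosome 7 (horizontal axis, Mb), with point area growing with the score and the 500 kb blocks shaded. LCC, TGFb and H2030 carry summits in the chromosome 10 block where SO1 has 0, and SO1 carries 39 in the chromosome 7 block where LCC has 0.

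The comparison of H2030 with LCC sets a second lung adenocarcinoma line against the LCC cells. H2030 differed from LCC in every mark and by far the most of the 3 conditions. Under the 10 kb distance, 415 promoter elements gained and 1289 lost H3K27ac, and 289 gained and 492 lost H3K4me3. The strongest H3K27ac loss was an element on chromosome 5 that was also strong in H3K4me3 in each H2087 condition. Of the LCC enhancer-like elements, 35.7% were kept.

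H2030 kept 62.7% of the LCC H3K4me3 summits (62.2 to 63.3), 35.0% of the H3K4me1 and 34.8% ± 3.18 (SD, n = 2) of the H3K27ac summits. In reverse, 63.8%, 37.6% and 37.2% ± 2.45 (SD, n = 2) of the H2030 summits were found in LCC. The H3K27ac shares lay below both replicate values of 56.1% and 69.8%. At equal list lengths, 36.8% of the summits of each LCC replicate were found in H2030, against the 65.9% and 65.4% that the replicates shared with each other. By the rule set beforehand, 747 elements gained and 2317 lost H3K27ac, and 564 gained and 893 lost H3K4me3. Without the strength condition the counts were 3972 and 5979 for H3K27ac and 7927 and 8262 for H3K4me3. Fewer of the elements called with it than in TGFb and SO1 had a summit within 10 kb, from 44.4% to 48.8%.

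The strongest H3K27ac loss, at 5:138861556-138861605, scored 315 and 468 in the LCC replicates, 433 in TGFb and 516 in SO1. The nearest H2030 H3K27ac summit lay 35866 bp away. Its H3K4me3 scores were 475 in LCC, 429 in TGFb and 524 in SO1, and the nearest H2030 H3K4me3 summit lay 36226 bp away. H2030 kept an H3K4me1 summit at 5:138862087 with a score of 11.1, and its neighbouring H3K4me3 peaks at 5:138897831 (258) and 5:138941631 (507) were present. Other H3K27ac losses were 2:65024399 (LCC 287 and 361), a pair of elements at 1:203121333-203122044 and 1:203123338 that share LCC summits (258 and 505), and 3:167742922 (251 and 301). LCC H3K4me3 scored only 6.30 at 2:65024399 and 29.3 at 1:203121333-203122044, against a list median of 189. It had no summit within 1 kb of 1:203123338 or 3:167742922, so these need not be promoters. The strongest H3K4me3 losses, 2:232260628-232260719, 17:46723796-46723903 and 5:8458037-8458058, scored 578, 566 and 558 in LCC.

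**Figure D5:**
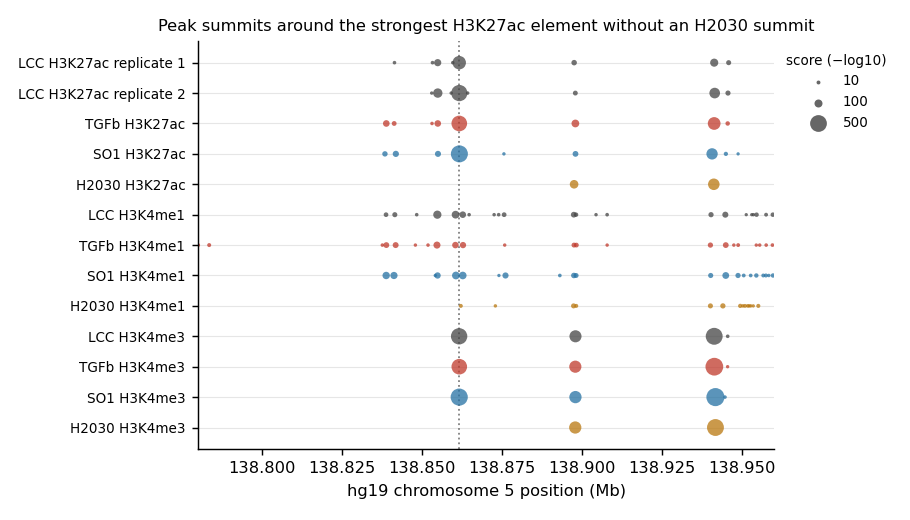
Peak summits of each library, one line each, in a part of hg19 chromosome 5 (horizontal axis, Mb), with point area growing with the score and a dotted line at the element 5:138861556-138861605. All LCC, TGFb and SO1 H3K27ac and H3K4me3 lists hold a summit there, and H2030 holds only H3K4me1, with a score of 11.1.

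H3K27ac gains in H2030 were led by 18:45529819 (score 471), 7:80572534 (429), 4:67430532-67431484 (419), 22:22901481-22901522 (417) and 6:136336027 (406). Their H2030 H3K4me3 scores were 2.64, 21.9, 42.9, 558 and 19.6, in the same order. At 4:67430532-67431484 the nearest LCC H3K27ac and H3K4me3 summits lay 833322 bp and 979512 bp away. H3K4me3 gains were led by 19:33685933 (636), 10:60273026 (602) and 8:58907344 (589). Both marks passed the strength condition together at 63 gained and 157 lost elements in H2030, at 1 gained and 0 lost in SO1, and at none in TGFb. Of the 1289 H3K27ac losses, 468 had no flanking H2030 summit as strong as the element, among them the chromosome 5 element, whose stronger flank scored 180.

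With no summit within 10 kb and no strength condition, 6713 of the 21674 H2030 enhancer-like elements were new and 7312 of the 16974 LCC elements were lost. LCC carried H3K4me1 at 31.1% (30.0 to 32.2) of the new elements, and H2030 at 26.8% (25.8 to 27.8) of the lost ones, against 85.6% and 85.9% of kept elements and 10.6% and 10.1% with shifted lists. Of all H2030 H3K4me1 summits 37.6% had an LCC one within 500 bp, and of all LCC ones 35.0% had an H2030 one. The shares at new and lost elements lay below these. The strongest new elements were 4:143013604 (435), 3:106935348 (411) and 2:228253265 (410). The strongest lost ones were 2:96308263 (LCC 262 and 369), 2:96099959 (255 and 315) and 3:167741995 (251 and 301), all present in TGFb and SO1. The last rests on the same LCC summits as 3:167742922, counted above as a promoter element through an SO1 H3K4me3 summit (15.4) alone. Loss affected 44.0% of replicate 1 and 45.4% of replicate 2 elements, above both replicate values. Without replicate 1, the lost elements numbered 13069.

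Dense H3K27ac regions, in which neighbouring summits lay within 12.5 kb, were described by their number of summits. The first region was 10:33519246-33630027 in LCC replicate 1 with 27 summits, 3:149238202-149380301 in replicate 2 with 46, 6:155308434-155492824 in TGFb with 45, 6:56502696-56632935 in SO1 with 32 and 5:58455237-58637038 in H2030 with 52. The second region of TGFb, 12:66236933-66356944, held 44 TGFb summits, against 18 and 28 in the LCC replicates, 22 in SO1 and 13 in H2030. Of the first 20 regions of replicate 1, 17 were among the first 100 of replicate 2, and 14 in the reverse direction. Among the first 100 of replicate 1 and of replicate 2 were 9 and 13 of the TGFb regions, 9 and 11 of the SO1 regions, and 1 and 1 of the H2030 regions. In the other direction, 8 of the first 20 regions of replicate 1 and 14 of replicate 2 were among the first 100 of TGFb, 10 and 12 among those of SO1, and 2 and 4 among those of H2030.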

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

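The values come from no test, so each alternative is judged by whether a share moved by more than the spread of the LCC replicates or its counting interval, or a count by more than 1.5 times. Of the alternative values, 72 stayed within that and 186 moved. The order of the conditions in LCC summits kept, TGFb highest and H2030 lowest, held for every mark in every setting. No paired analysis was possible because the results come from no test, and the inputs that share replicate numbers with LCC H3K27ac were not analysed here. The depth of each library is unknown, and its effect on the counts was not tested. The cause of the changes below was not tested, except that a smaller distance for sharing can only lower a share, and a larger distance without a summit can only lower a count.

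With summits shared within 250 bp instead of 500 bp, the LCC replicates shared 61.1 and 49.2%. LCC summits kept, in the order H3K27ac, H3K4me1 and H3K4me3, came to 55.4, 47.9 and 85.9 in TGFb, 48.7, 41.8 and 80.4 in SO1, and 29.0, 24.3 and 57.6 in H2030 (%). The reverse shares were 46.1, 47.5 and 77.6 in TGFb, 48.8, 46.6 and 73.1 in SO1, and 31.2, 26.1 and 58.6 in H2030 (%).

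With only peaks that score at least 10, the replicates shared 75.3 and 60.1%. In the same order of marks, LCC summits kept were 72.2, 61.1 and 92.9 in TGFb, 66.4, 58.7 and 88.6 in SO1, and 42.4, 31.7 and 68.0 in H2030 (%), and the reverse 52.5, 62.0 and 86.3 in TGFb, 52.6, 57.2 and 80.4 in SO1, and 43.5, 42.1 and 68.7 in H2030 (%). Gained and lost promoter elements numbered 159 and 297 (H3K27ac) and 110 and 113 (H3K4me3) in TGFb, 246 and 415 (H3K27ac) and 138 and 141 (H3K4me3) in SO1, and 671 and 1565 (H3K27ac) and 327 and 559 (H3K4me3) in H2030. LCC enhancer-like elements kept, and elements found in LCC, were 87.3 and 58.2 in TGFb, 79.2 and 56.2 in SO1, and 35.2 and 41.3 in H2030 (%). Distal elements without a summit within 10 kb, with the share carrying H3K4me1, came to 5421 new (72.5%) and 376 lost (81.4%) in TGFb, 5506 new (61.0%) and 957 lost (51.7%) in SO1, and 4143 new (31.4%) and 4167 lost (16.3%) in H2030.

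With lists of equal length, the replicates shared 65.9 and 65.4%. LCC summits kept were 61.7, 61.9 and 87.9 in TGFb, 57.7, 56.7 and 82.9 in SO1, and 36.8, 36.1 and 63.5 in H2030 (%), and the reverse 61.2, 61.9 and 87.8 in TGFb, 57.4, 56.7 and 82.8 in SO1, and 36.6, 36.2 and 63.5 in H2030 (%), so that the order of TGFb and SO1 in the reverse H3K27ac share turned. All counts of gained and lost elements stayed within 1.5 times. Enhancer-like elements kept and found in LCC were 80.9 and 68.7 in TGFb, 73.5 and 64.7 in SO1, and 36.4 and 38.4 in H2030 (%). With a kept distance of 500 bp they were 73.9 and 58.2 in TGFb, 64.3 and 60.1 in SO1, and 29.0 and 35.6 in H2030 (%).

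Gained and lost promoter elements depended most on the strength condition and the distance. A window of 2500 bp gave 83 and 366 (H3K27ac) and 48 and 35 (H3K4me3) in TGFb, 139 and 397 (H3K27ac) and 76 and 59 (H3K4me3) in SO1, and 687 and 2182 (H3K27ac) and 381 and 678 (H3K4me3) in H2030. No strength condition gave 1976 and 1059 (H3K27ac) and 4235 and 1679 (H3K4me3) in TGFb, 2150 and 1683 (H3K27ac) and 5427 and 2902 (H3K4me3) in SO1, and 3972 and 5979 (H3K27ac) and 7927 and 8262 (H3K4me3) in H2030, so that TGFb and SO1 H3K27ac and SO1 H3K4me3 turned from more lost to more gained. Among the distances added after seeing the data, no summit within 5 kb gave 30 and 97 (H3K27ac) and 6 and 3 (H3K4me3) in TGFb, 74 and 150 (H3K27ac) and 25 and 17 (H3K4me3) in SO1, and 509 and 1617 (H3K27ac) and 335 and 580 (H3K4me3) in H2030. At 10 kb the counts were 24 and 37 (H3K27ac) and 4 and 0 (H3K4me3) in TGFb, 60 and 87 (H3K27ac) and 22 and 9 (H3K4me3) in SO1, and 415 and 1289 (H3K27ac) and 289 and 492 (H3K4me3) in H2030. At 25 kb they were 12 and 23 (H3K27ac) and 2 and 0 (H3K4me3) in TGFb, 39 and 49 (H3K27ac) and 17 and 4 (H3K4me3) in SO1, and 290 and 817 (H3K27ac) and 230 and 337 (H3K4me3) in H2030. Distal elements at 25 kb, also added after seeing the data, came to 2877 new (74.6%) and 398 lost (88.2%) in TGFb, 2638 new (64.9%) and 1207 lost (51.7%) in SO1, and 3932 new (24.1%) and 4976 lost (22.4%) in H2030.

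The shares of H3K27ac summits are means over the LCC replicates, so 12 of the values that stayed, those with replicate 1 or 2 left out, could not have moved and say nothing about stability. H3K27ac elements gained and lost ranged over 358 to 371 and 519 to 661 in TGFb, 475 to 546 and 633 to 706 in SO1, and 962 to 1074 and 2217 to 2284 in H2030. With no summit within 10 kb, the ranges were 32 to 84 and 15 to 41 in TGFb, 84 to 126 and 66 to 85 in SO1, and 464 to 607 and 1150 to 1171 in H2030. Enhancer-like elements kept and found in LCC ranged over 73.5 to 76.1 and 43.7 to 58.9 in TGFb, 60.6 to 66.4 and 48.1 to 60.7 in SO1, and 29.5 to 32.5 and 31.2 to 37.3 in H2030 (%). Distal elements numbered 6384 to 10004 new (78.9 to 83.2%) and 1748 to 2556 lost (78.8 to 79.1%) in TGFb, 5570 to 8160 new (72.3 to 77.9%) and 3312 to 5071 lost (50.8 to 62.3%) in SO1, and 7158 to 8622 new (33.2 to 38.6%) and 9219 to 13069 lost (25.2 to 25.5%) in H2030. Leaving out a replicate loosens the requirement that both mark an LCC element, and for new or gained elements that neither does. It also changes the scores that the strength condition uses. With either replicate left out, losses at 10 kb were below the 87 of SO1 and the 1289 of H2030. In TGFb they were 15 without replicate 1 and 41 without replicate 2, beside 37 with both.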

Other observations

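The tests of displaced summits, of the distance to stronger flanking summits, of missed LCC peaks, of the number of H3K27ac peaks in TGFb and of H3K4me1 peaks in SO1, of stretches without H3K4me1 and of missing DNA were chosen only after the results were seen.

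SO1 H3K27ac shared more summits with TGFb than with LCC. At equal list lengths, 63.8% (Wilson 95% interval 63.4 to 64.3) of the SO1 summits had a TGFb summit within 500 bp, against 56.8% and 58.0% with LCC replicates 1 and 2. TGFb in turn shared 63.7% with SO1 and 59.2% and 63.3% with the LCC replicates, which shared 65.9% and 65.4% with each other. For H3K4me1, SO1 shared 58.4% with TGFb and 56.7% with LCC, and for H3K4me3 83.8% and 82.8%. The difference was not tested, since TGFb and SO1 have 1 library each per mark. The median H3K27ac scores were 30.1 in SO1, 20.9 in TGFb, and 12.6 and 13.5 in the LCC replicates.

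Both LCC H3K27ac lists held clusters of summits in stretches that the other lists mostly lack. With summits of replicate 1 joined within 25 kb, 6 stretches had at least 5 summits in each replicate and no H3K4me1 summit in any condition, a rule chosen after the values were seen. TGFb and H2030 had 0 H3K27ac summits in all 6. TGFb H3K4me3, however, held from 1 to 4 summits in each except 11:51572147-51591117, and LCC H3K4me3 held summits in every one. At 16:46386846-46435330, the region ranked 3 among the dense regions of replicate 1, the LCC replicates had 23 and 17 H3K27ac summits, LCC H3K4me3 11 and SO1 H3K27ac 2. At 2:92269488-92325099 the counts were 17, 19, 11 and 1. The others were 10:42360763-42408277, 10:42527462-42546090, 11:51572147-51591117 and 19:27732109-27740226. These stretches lie beside centromeres, where repeats are dense.

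Loss of H3K27ac in TGFb was the first pattern weighed. Displaced summits of wide peaks may account for part of the 463 losses at 1 kb, since 92.0% (89.2 to 94.1) had a TGFb summit between 1 and 10 kb away, against 61.4% (60.5 to 62.2) of the strong LCC elements that TGFb marks. Of the 37 left at 10 kb, 22 lie in stretches without H3K4me1 in any condition, as background peaks in LCC could. TGFb H3K4me3 summits also lay in such stretches, so signal there was not confined to LCC. Joined peaks are argued against for these 22, as far as scores of different lists can be compared. Of these, 6 had only weaker flanking TGFb summits and 16 had a stronger one no nearer than 50445 bp. The upper quartile of H3K27ac scores was 34.0 and 49.0 in the LCC replicates and 96.3 in TGFb, and the depths are unknown. Too few peaks in TGFb is argued against by its 68118 summits. For the other 15, with a stronger TGFb summit within 38902 bp, joined peaks and true loss cannot be told apart without peak widths, and an effect of TGF-β1 stays open.

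H3K4me1 at distal elements that lack H3K27ac was the second pattern. LCC H3K4me1 lay at 77.2% (76.1 to 78.3) of the TGFb-new elements, and at 95.5% and 97.7% of the TGFb elements that replicate 1 or replicate 2 missed and the other found. Peaks missed by both replicates would be weaker still, so the lower share decides nothing, and peaks missed in LCC and new H3K27ac cannot be told apart. Lost elements kept H3K4me1 in 87.8% for TGFb and 59.5% for SO1, a difference of 28.3 percentage points, and with the TGFb H3K4me1 list reduced to the number of SO1 peaks the TGFb share was still 83.5% (80.8 to 85.9), which argues against fewer H3K4me1 peaks in SO1 as the whole cause. The lost shares were 78.8% and 62.3% without replicate 1, 79.1% and 50.8% without replicate 2, and 81.4% and 51.7% with scores of at least 10, and a difference between SO1 and TGF-β1 treatment rests on 1 library each.

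The blocks with LCC summits and almost none in SO1 were the third pattern. Fewer peaks throughout SO1 cannot be the cause, since the median ratio of SO1 to LCC summits over eligible blocks was 97.4%. DNA of the block missing in SO1 and loss of the marks from DNA that is present cannot be told apart, as the blocks were chosen for having almost no SO1 summits and the input libraries were not analysed here. Of the 12 blocks, 7 held no SO1 summit and 5 a single one with scores from 4.38 to 52.0, 0 of them at or above the median of its list. The SO1 H3K4me3 losses at 10:54074109-54074624 and 8:13133868-13133905 lie in such blocks, so the same limit holds for them. No biological explanation was tested.

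Between H2030 and LCC, 81 of 3573 eligible blocks had summits in H2030 and almost none in LCC, and 32 of 3820 the reverse. No summit at all lay in 64 and 18 of them, and missing DNA could not be checked there either. The reverse blocks include 10:42000001-42500000 and 16:46000001-46500000, which hold stretches beside centromeres described above. The block 9:87500001-88000000 had 56 LCC and 1 H2030 summits, and 7:80000001-80500000 had 111 in H2030 and 3 in LCC.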
